A study of Mus musculus with 5 samples.

How the data were processed

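Messenger RNA of peritoneal macrophages sorted by flow cytometry from C57BL/6 mice was sequenced with a strand-specific kit, per the labels. The 5 libraries fall into 2 groups: 3 wild-type (wt) libraries and 2 libraries with a homozygous Samhd1 deletion (del/del) together with a homozygous cGAS-GFP knock-in (ki/ki), called mutant here. The labels give wt 1 as a 13-week male, wt 2 as a 13-week female, wt 3 as a 9-week female and both mutants as 8-week females. Ages and sexes differ between some replicates, but the labels do not otherwise say that each came from its own animal, so p-values measure the spread between these samples.

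Per the submitters' processing notes, the authors used STAR, featureCounts from Subread, DESeq 1.6.1 and the mouse build mm10. Aligner settings, annotation release and the strand setting of the counting are not given in the sources used here. The deposited signal of each library is a read count per gene divided by 1 size factor per library, as judged from the values. All values in a library were whole multiples of what 1 read is worth: 100% of values came out whole within 0.001 reads, and reads were recovered in this way. The authors' deposited table also gives a log2 fold change, here read as wt over mutant because 100% of the authors' calls carry the sign of the group means. The authors' deposited p-value and adjusted p-value accompany it, per the file headers, and how they were adjusted is not given in the sources used here. The GC content in percent that the authors deposited with each gene, per the file headers, was not used. The authors' mean over libraries was above 0 in all 3266 rows in which the 5 libraries hold 0 reads, so their fit drew on further libraries that are not analysed here.

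The table used here lists 30478 genes on chromosomes 1 to 19, of which 370 have no symbol. Genes on X, Y and the mitochondrial genome were not analysed here, so the sex labels were not checked against Xist and Ddx3y, and the list of sex-linked genes had 0 members tested. Chromosome positions are those of GENCODE M21 on GRCm38, matched by Ensembl identifier, which was found for 97.1% of genes. Only 2.27% of those genes had the same start in the deposited table, so its coordinates were not printed. Recovered reads came to 33119434, 30817815 and 30026622 for wt 1 to 3 and 28517346 and 27282354 for mutants 1 and 2. Reads of a gene as a share of the library total are given as CPM. A count of 0 allows up to 3 reads, which is 0.091 to 0.11 CPM in these libraries, and this limit covers counting error only. The mean chi-square per gene between replicates was 14.3 to 26 in wt and 61.6 between the mutants, so no pair of libraries agreed within sampling noise and each counted as 1 sample.

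The test fixed before the data were examined was edgeR's quasi-likelihood test on counts. The values turned out to be normalized, so the test used here was limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(normalized count + 2). Genes at 10 or more in at least 2 libraries entered, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A fold change is therefore that of the normalized count + 2, which understates the change of genes with few reads. The edgeR 4.0.16 test fixed beforehand, with TMM factors, was run on the recovered reads and made an alternative after the data were seen. It called 615 genes higher and 665 lower in the mutant. Of 30 gene lists fixed before the data were examined, 29 were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Camera compares a list with all other genes, and fry tests a list by itself. Both were run on the limma values, whereas camera was planned on the edgeR fit. With an estimated correlation, camera also uses the few residual degrees of freedom of these libraries. Erythroid and platelet markers had an estimated correlation of -0.236, below the preset 0.01, yet unadjusted camera p went from 0.00146 to 0.0476. A call lost there therefore need not come from correlation between genes. Counts of list members are given over all genes tested and adjusted over the list alone.

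Genes were named by a rule fixed before the data were examined. The named genes were Samhd1 and Cgas, the 10 highest and 10 lowest fold changes among called genes of at least 5 CPM whose groups did not overlap, and, in each list with a called member, the 4 members of lowest adjusted p plus the most abundant member of lists of other cell types. Predicted genes with Gm or Rik symbols, pseudogenes and receptor segments were left out, and Ifih1, Ddx58, Sting1, Mavs and Ifnb1 were added because the series title speaks of their pathway. Other genes named here are list members or were chosen after their values were seen, and values of some single list members are not reported here. Genes of families with near-identical members (Ly6, Ifi200, Slfn, Phf11, Apol9, Gbp, Tgtp, Oas, Ifit, H2-Q and histone genes) can share reads, so their single values are uncertain, as are those of overlapping antisense genes.

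The alternatives were RLE factors, no filter on low values, DESeq2 1.42.0, limma-voom, leaving out each library in turn, the replicate number as a block, a robust prior and a test against a 1.5-fold change. TMM scaling and pseudocounts of 0.5 and 8 were added after the data were seen. Calls of single genes with a library left out were looked up only for the genes named by the rule. Leaving out a wt library lowers the degrees of freedom and gives the spread between the mutants more weight. A call can thus be lost while the fold change stays. On simulated counts with 200 single genes changed and 1 list of genes lowered, limma recovered 63.8% of 2-fold and 91.8% of 4-fold changes among 14756 genes for mutant against wt. Of its calls there, 7.81% fell on unchanged genes. The simulation drew genes independently and gave both groups the same dispersion, unlike these libraries, so its shares need not carry over to them. Figures were drawn with matplotlib 3.10.9.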

Results

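Cells labelled as peritoneal macrophages, the phagocytes of the abdominal cavity, were profiled by strand-specific mRNA sequencing. There were 3 wt libraries and 2 libraries that carry both a Samhd1 deletion and a cGAS-GFP knock-in. SAMHD1 is a dNTP hydrolase that restrains the activation of interferon responses, and cGAS is the cytosolic DNA sensor that signals through STING. The series title places the study in the question of whether activation of the RNA sensor MDA5 in SAMHD1-deficient cells depends on cGAS and STING. The 2 genetic changes occur together in these libraries, so the comparison of mutant with wt cannot assign a difference to either. Depth was 30026622 to 33119434 recovered reads in wt and 27282354 to 28517346 in the mutant.

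Interferon-stimulated genes were far lower in mutant macrophages than in wt macrophages. Of 58 tested, 57 fell, with a list median log2 fold change of -1.99, and most interferon-inducible GTPases and MHC class I genes fell with them. As lists, those last 2 were not called once the correlation was estimated (adjusted p = 0.388 and adjusted p = 0.24 with an estimated correlation). That setting also lowers the degrees of freedom of camera, so correlation need not be the reason. Fry gave these 2 lists unadjusted p = 0.000217 and 0.000239. The RNA sensors Ifih1 (MDA5), Ddx58 (RIG-I) and Dhx58 (LGP2) fell, whereas the adaptors Mavs and Sting1 differed by less than the test could separate. Of 24 complement and phagocytic receptor genes, 7 rose, among them Cd163 and Mertk, and 3 fell, among them Axl, and the list was not called (camera adjusted p = 0.152). In all, 14977 genes were tested by limma, of which 556 were higher and 732 lower in the mutant, 156 and 338 of them by at least 2-fold.

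Both targeted genes were low in each mutant library. Samhd1 (GENCODE M21, GRCm38, chromosome 2, 157097533 to 157135265, minus strand) read 1279 and 1431 normalized counts in mutants 1 and 2 against 17820, 16780 and 18270 in wt 1 to 3. Its log2 fold change was -3.70 (SE 0.0798, limma adjusted p = 1.44e-05), a 13.0-fold difference. Cgas (GENCODE M21, GRCm38, chromosome 9, 78430526 to 78443237, minus strand) read 184 and 85.05 in the mutants against 974.1, 1211 and 967.7 in wt. Its log2 fold change was -3.04 (SE 0.308, limma adjusted p = 0.00391). In the authors' deposited table the log2 fold changes, wt over mutant, were 3.47 for Samhd1 and 1.68 for Cgas. Both genes are known to be inducible by interferon, and 5 of the 58 interferon-stimulated genes fell by more than Samhd1 and 7 by more than Cgas.

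**Figure D1:**
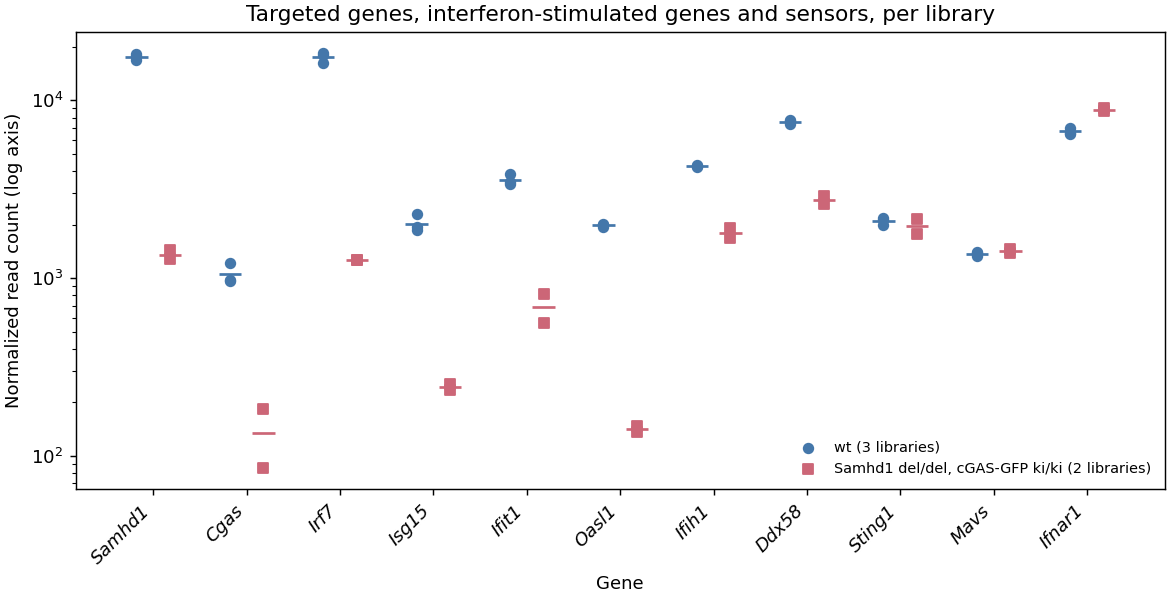
Normalized read counts (log axis) of 11 genes in 3 wt libraries (circles) and 2 mutant libraries (squares), with a horizontal line at each group mean. Irf7 stands at 1260 and 1256 in the mutants against 16210 to 18450 in wt, while Sting1 and Mavs overlap between the groups.

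The fall of the interferon-stimulated genes was uniform across the list. All 58 tested members had a negative fold change, from -5.23 to -0.53, and 58 passed when adjusted over the list alone. No member was higher by limma at an adjusted or unadjusted p, nor by edgeR, DESeq2 or limma-voom. Irf7, the transcription factor that amplifies interferon production, fell from 17550 ± 1180 (SD, n = 3) to 1258 ± 3.42 normalized counts (SD, n = 2; log2 -3.80, SE 0.0784, limma adjusted p = 1.44e-05). The RNA-binding oligoadenylate synthetase-like gene Oasl1 fell from 1989 ± 40.9 to 142 ± 6.82 (limma adjusted p = 1.44e-05) and Oasl2 by 2.42 on the log2 scale. Ifi44 had the lowest value of the list, 22.46 ± 1.32 against 923 ± 137. The ubiquitin-like modifier Isg15 (-3.04), its protease Usp18 (-2.87), the Z-form nucleic acid sensor Zbp1 (-3.51) and the sialic acid receptor Siglec1 (-2.23) also fell. Changes were smaller for the signal transducers Stat2 (-1.86) and Irf9 (-0.53). The chemokine Cxcl10 had a log2 fold change of -1.31 that missed the threshold over all genes (limma adjusted p = 0.0564).

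As a list, interferon-stimulated genes stood below all other genes (camera adjusted p = 4.6e-58), and this was the 1 list of 29 still called with an estimated correlation (adjusted p = 0.0456 with an estimated correlation). Its median stood at -2.07 in mutant 1 and -1.98 in mutant 2 relative to the wt mean, while the wt libraries stood between -0.00509 and 0.00621. The authors' deposited table also calls all 58. The share of reads on Rn18s (18S ribosomal RNA) moved with the genotype too, at 5.28% and 4.04% in mutants 1 and 2 against 0.599%, 1.47% and 1.64% in wt 1 to 3.

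Among nucleic acid sensors and their adaptors, 7 of 21 tested genes fell, 1 rose and 13 did not pass, with 7 lower and 1 higher when adjusted over the list alone. Ifih1, which encodes MDA5, fell from 4262 ± 45 to 1793 ± 171 normalized counts (log2 -1.25, SE 0.0788, limma adjusted p = 0.00052). Ddx58 fell by 1.46, Dhx58 by 1.72 and the double-stranded RNA receptor Tlr3 by 1.48 on the log2 scale. The RNA editor Adar, the exonuclease Trex1 and the adaptor Myd88 fell as well. Sting1 (-0.10, limma adjusted p = 0.521), Mavs (0.06, limma adjusted p = 0.593), Tbk1 (-0.11) and Irf3 (0.04) did not pass. The list was lower by camera (adjusted p = 0.00305), a call lost on estimation (adjusted p = 0.546 with an estimated correlation).

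Of 18 interferons and receptors on the list, 9 were in the table, and of these only the 4 receptor genes had enough reads to test. Ifnar1, a chain of the type I interferon receptor, rose from 6678 ± 296 to 8836 ± 249 (log2 0.40, limma adjusted p = 0.0242), also when adjusted over the list alone. Ifnar2, Ifngr1 and Ifngr2 had log2 fold changes of 0.20, 0.39 and 0.26 that did not pass. Ifnar1 was not called without wt 1, wt 2 or wt 3 (limma adjusted p = 0.139, 0.0641 and 0.136). The list was higher by camera (adjusted p = 0.0293), but not with an estimated correlation (adjusted p = 0.695 with an estimated correlation) or without mutant 2 (camera adjusted p = 0.153). Ifnb1, which encodes interferon beta, had 1 read in mutant 1 and 0 in the other 4 libraries, so no difference was detectable at this depth.

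Interferon-inducible GTPases, which act on pathogen vacuoles, fell in 12 of 16 tested cases, and in 14 when adjusted over the list alone. Tgtp2 fell from 1122 ± 12 to 106.5 ± 1.2 (log2 -3.37, SE 0.0858, limma adjusted p = 2.46e-05). Ifi47 (-1.76), Irgm1 (-1.59), Igtp (-1.54) and Gbp6 (-4.03) fell, whereas Gbp3, Gbp5 and Gbp7 had values of -0.92, -0.61 and -0.47 that did not pass. The list median was -1.56 (camera adjusted p = 2.11e-15; adjusted p = 0.388 with an estimated correlation).

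MHC class I antigen presentation fell in 18 of 20 tested genes, and in all 20 when adjusted over the list alone, with a median of -0.93. The peptide transporter gene Tap1 fell from 8016 ± 447 to 2677 ± 149 (log2 -1.58, SE 0.0783, limma adjusted p = 0.000204). The immunoproteasome subunit Psmb8 (-1.12), the class I transactivator Nlrc5 (-1.49) and H2-Q4 (-1.67) fell too. The list was lower by camera (adjusted p = 5.7e-18; adjusted p = 0.24 with an estimated correlation). In contrast, 0 of 12 MHC class II genes passed limma at an adjusted or unadjusted p, and 0 passed by edgeR, DESeq2 or limma-voom or adjusted over the list alone. The class II median was -0.29 (camera adjusted p = 0.512, and adjusted p = 0.934 with an estimated correlation). Relative to the wt mean, the class II median stood at -0.53 in mutant 1 and 0.22 in mutant 2. The wt libraries stood between -0.221 and 0.16, so the 2 mutants lay on opposite sides of them. The median over all libraries therefore averages 2 mutants that differ, and does not show that class II was unchanged in each. The difference between the 2 classes was not itself tested.

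**Figure D2:**
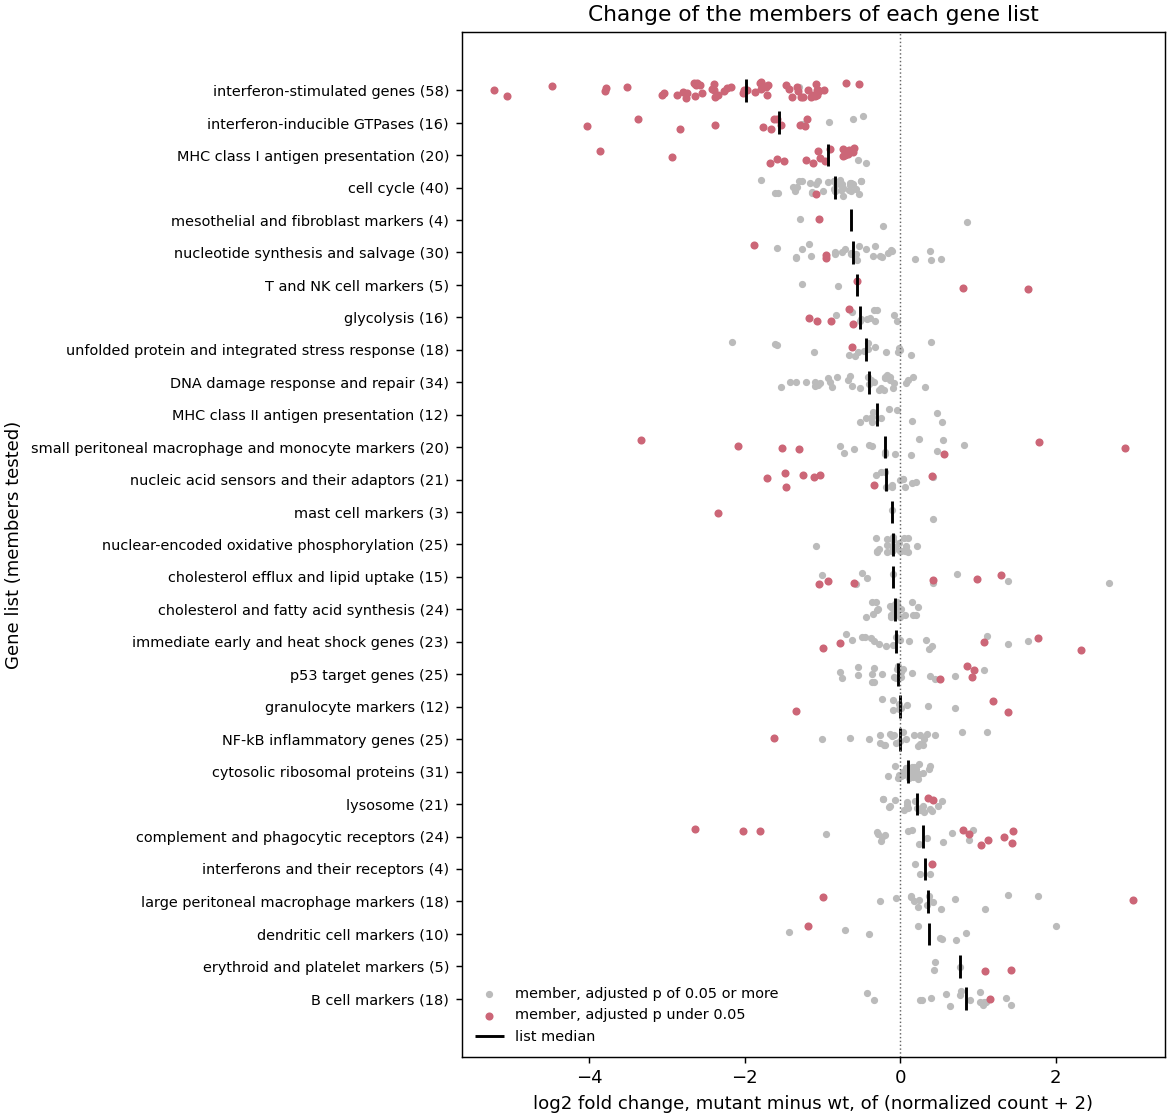
Log2 fold changes, mutant minus wt, of (normalized count + 2) for the tested members of 29 gene lists; red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. The interferon-stimulated genes have a median of -1.99 and lie entirely to the left of 0.

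Proliferation genes as a list stood lower in both mutant libraries, and further in mutant 2. All 40 cell cycle genes had negative fold changes, but the replication clamp gene Pcna alone passed (13770 ± 978 against 6722 ± 2370, log2 -1.08, limma adjusted p = 0.0305), or 17 genes when adjusted over the list alone. The replication genes Ccne1 (-1.79), Mcm4 (-1.09) and Mcm6 (-1.26) missed the threshold, with limma adjusted p of 0.0566 to 0.0688. By DESeq2 they were called lower (adjusted p = 0.000966, 0.00387 and 0.00383). Without mutant 2 their log2 fold changes were -0.98, -0.57 and -0.63, with 1 mutant library left and so no spread between mutants. Relative to wt the list median stood at -0.25 in mutant 1 and -1.44 in mutant 2. The list was lower by camera (adjusted p = 1.17e-09), but not at its estimated correlation of 0.989 (adjusted p = 0.717 with an estimated correlation). The Rn18s share was higher in mutant 1 (5.28%) than in mutant 2 (4.04%), and higher in both than in wt. Mki67, a proliferation marker, read 15380 and 6795 in mutants 1 and 2 against 15360 to 16430 in wt. Pcna was no longer called without wt 1, wt 2 or wt 3 (limma adjusted p = 0.134, 0.119 and 0.121).

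Nucleotide synthesis and salvage genes included 3 that fell, 17 lower and 3 higher when adjusted over the list alone, and a median of -0.60 over 30 tested (camera adjusted p = 3.6e-05; adjusted p = 0.717 with an estimated correlation). The list median was -0.28 in mutant 1 and -1.01 in mutant 2. Dck, the kinase that starts deoxycytidine salvage, fell from 7756 ± 382 to 2164 ± 752 (log2 -1.88, SE 0.198, limma adjusted p = 0.00452). The pyrimidine nucleotidase Nt5c3 (-0.96) and the purine phosphorylase Pnp (-0.95) fell, and Dctd (-1.26, limma adjusted p = 0.0618) did not pass. In DNA damage response and repair, 0 of 34 genes passed limma or edgeR or limma-voom, 0 when adjusted over the list alone, 11 were lower by DESeq2 and 20 lower and 1 higher at an unadjusted p. That list had a median of -0.41 (camera adjusted p = 7.1e-05; adjusted p = 0.717 with an estimated correlation), at -0.25 in mutant 1 and -0.59 in mutant 2. Among 25 p53 target genes, 4 rose and 0 fell, or 6 and 4 when adjusted over the list alone. The unadjusted limma count of p53 targets was 7 higher and 8 lower, with 0 lower by edgeR and limma-voom and 3 by DESeq2. The RNA-binding protein gene Zmat3 rose by 0.51, Sesn1 by 0.95, the death receptor Fas by 0.93 and Trp53inp1 by 0.86 on the log2 scale. None of these 4 was called without wt 1, wt 2 or wt 3 (limma adjusted p = 0.0517 to 0.136). Their list median was -0.03 and the mean 0.07, and camera made no call (adjusted p = 0.831).

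Glycolysis fell in 5 of 16 genes, or 12 when adjusted over the list alone, with all 16 fold changes negative and a median of -0.51. Phosphofructokinase Pfkp fell from 5371 ± 292 to 2427 ± 738 (log2 -1.18, limma adjusted p = 0.0157), and the hexokinase Hk2 (-0.61), the glucose transporter Slc2a1 (-0.89) and Tpi1 (-0.65) fell. None of these 4 was called without wt 1, wt 2 or wt 3 (limma adjusted p = 0.07 to 0.159). Camera called the list lower (adjusted p = 5.71e-06; adjusted p = 0.695 with an estimated correlation), with medians of -0.25 in mutant 1 and -0.75 in mutant 2. The unfolded protein and integrated stress response had 1 of 18 genes lower, Creld2 (-0.61, limma adjusted p = 0.0389, or 0.115 to 0.148 without 1 wt library), and 10 lower and 1 higher when adjusted over the list alone. The chaperone Hspa5 (-0.55) and the stress transcription factor Ddit3 (-1.11) did not pass. The list was lower by camera (adjusted p = 0.0027; adjusted p = 0.717 with an estimated correlation). Among 23 immediate early and heat shock genes, Egr1, Egr3 and Ier2 rose and the chaperones Hsph1 and Hsp90aa1 fell, or 4 rose and 3 fell when adjusted over the list alone. Limma-voom called Egr1 and Ier2 higher but not Egr3. Egr1 went from 967.1 ± 189 to 5423 ± 3570 (log2 2.33, limma adjusted p = 0.0248), with 2902 in mutant 1 and 7945 in mutant 2, and was not called without wt 1, wt 2 or wt 3 (limma adjusted p = 0.106, 0.101 and 0.103). Nor were Ier2, Hsph1 and Hsp90aa1 called without any of these (0.123 to 0.143), and Ier2 (0.0665) and Hsp90aa1 (0.0504) were not called with a robust prior. The list median was -0.05, the mean 0.23, and camera made no call (adjusted p = 0.888).

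**Figure D3:**
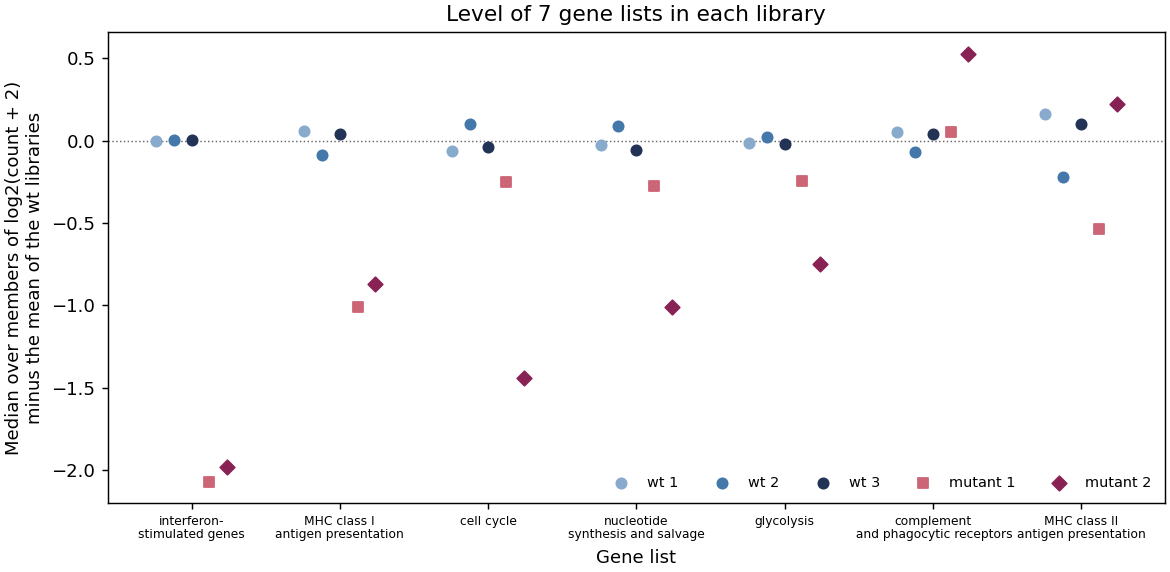
Median over list members of log2(normalized count + 2) minus the mean of the wt libraries, for 7 gene lists in each of the 5 libraries. The interferon-stimulated genes stand at -2.07 and -1.98 in the mutants, whereas the cell cycle list stands at -0.25 in mutant 1 and -1.44 in mutant 2.

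Genes of the complement and phagocytic receptor list shifted in both directions, and Axl was the only receptor among those that fell. Of 24 complement and phagocytic receptor genes, 7 rose and 3 fell, or 10 and 6 when adjusted over the list alone. Stab1, a scavenger receptor, rose from 29940 ± 6360 to 80550 ± 10500 (log2 1.44, SE 0.181, limma adjusted p = 0.00889). The haemoglobin scavenger receptor Cd163 (1.45), the efferocytosis receptor Mertk (1.13), the bridging ligand Gas6 (0.81), the inhibitory Fc receptor Fcgr2b (1.33), Colec12 (1.05) and Tlr2 (0.89) rose. Axl, the interferon-inducible relative of Mertk, fell from 5982 ± 1510 to 1466 ± 448 (log2 -2.03, limma adjusted p = 0.0107), and the complement genes C4b (-1.80) and Cfb (-2.64) fell. Stab1 was not called without wt 1 or wt 3 (limma adjusted p = 0.0621 and 0.0661), nor Cd163 without wt 1, wt 2 or wt 3 (limma adjusted p = 0.0679, 0.0519 and 0.0522). Axl (0.0724 and 0.0659) and Gas6 (0.0952 and 0.0843) were likewise not called without wt 1 or wt 3. The Rn18s share (5.28% and 4.04%) and the immunoglobulin gene Ighm were higher in the same 2 libraries. The receptor list was not called by camera (adjusted p = 0.152), but was without wt 1 or wt 3 (camera adjusted p = 0.0408 and 0.0463, at the preset correlation). Its median was 0.29 over all libraries and 0.53 without mutant 1. Over all libraries it had adjusted p = 0.911 with an estimated correlation of 0.418.

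Genes of cholesterol efflux and lipid uptake were split, with 3 of 15 higher and 3 lower, or 6 and 6 when adjusted over the list alone. The fatty acid binding proteins Fabp5 (0.99) and Fabp4 (1.30) and the ubiquitin ligase Mylip (0.42) rose. The lipid droplet coat gene Plin2 (-0.60), the fatty acid transporter Cd36 (-0.93) and lipoprotein lipase Lpl (-1.05) fell, Cd36 from 21920 ± 224 to 11620 ± 2390 (limma adjusted p = 0.0115). Cd36 was not called without wt 1, wt 2 or wt 3 (0.0623 to 0.0823), nor were Plin2, Lpl and Fabp5 without wt 1 or wt 3 (0.0525 to 0.102). The list median was -0.09, its mean 0.18, and camera made no call (adjusted p = 0.831). In the lysosome list, Npc1 (0.36, limma adjusted p = 0.029) and the glucosidase gene Gaa (0.43) rose, 2 of 21 tested and 2 when adjusted over the list alone, but neither was called without wt 1, wt 2 or wt 3 (0.0804 to 0.158). Camera called the lysosome list higher (adjusted p = 0.0127; adjusted p = 0.717 with an estimated correlation), though not without mutant 2 (camera adjusted p = 0.0963).

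Markers of resident large peritoneal macrophages included 1 of 18 that rose and 1 that fell, or 2 and 1 when adjusted over the list alone. The scavenger receptor Marco rose from 6.47 ± 2.25 to 68.28 ± 34.9 (log2 2.99, limma adjusted p = 0.0119) and the adhesion gene Icam2 fell from 337.5 ± 31.2 to 170.3 ± 31.8. Marco was not called without wt 1 or wt 3 (limma adjusted p = 0.0764 and 0.0677), nor Icam2 without wt 1, wt 2 or wt 3 (0.0595 to 0.11). Gata6 and Timd4 of the same list had 0 reads in all 5 libraries. A change of this list therefore does not by itself show a change in resident macrophages. Adgre1, which encodes F4/80, stood at 48510 ± 4660 and 55220 ± 11600 and did not pass (limma adjusted p = 0.469). The list was higher by camera (adjusted p = 0.0127; adjusted p = 0.546 with an estimated correlation), though not without mutant 2 (camera adjusted p = 0.0874). Of 20 markers of small peritoneal macrophages and monocytes, 4 fell and 3 rose, or 5 and 4 when adjusted over the list alone. The high-affinity Fc receptor Fcgr1 fell from 10920 ± 570 to 3835 ± 698 (log2 -1.52, SE 0.12, limma adjusted p = 0.00123), along with Ly6c2 (-2.08), Plac8 (-3.33) and Folr2 (-1.30). The transglutaminase F13a1 (2.89), lysozyme Lyz1 (1.78) and the mannose receptor Mrc1 (0.57) rose, with F13a1 at 2969 in mutant 1 and 6713 in mutant 2. F13a1 and Folr2 were not called without wt 1 (limma adjusted p = 0.0545 and 0.0535), and Mrc1 was not without wt 1, wt 2 or wt 3 (0.0606 to 0.168). The list was not called by camera (adjusted p = 0.43).

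Among markers of other cell types, some rose and others fell. B cell markers had a median of 0.84 over 18 tested, with medians of 1.07 in mutant 1 and 0.36 in mutant 2. Ighm, the constant region of IgM, rose from 2410 ± 371 to 5383 ± 890 (log2 1.16, limma adjusted p = 0.0105) as the only called member, or 3 members when adjusted over the list alone. Ighm was not called without wt 1 or wt 3 (limma adjusted p = 0.0742 and 0.0676). It averaged 128 CPM, while the light chain gene Igkc averaged 1.83 CPM and did not pass (1.43, limma adjusted p = 0.0566). The rise of Ighm alone therefore does not show more B cells. The B cell list was higher by camera (adjusted p = 0.00327; adjusted p = 0.695 with an estimated correlation), though not without mutant 1 (camera adjusted p = 0.337). In erythroid and platelet markers, Gp1ba (1.10) and Ppbp (1.43) rose among 5 tested, or 4 when adjusted over the list alone. Gp1ba (0.113 to 0.145) and Ppbp (0.064 to 0.153) were not called without wt 1, wt 2 or wt 3, nor Ppbp without mutant 2 (0.0898). That list was higher by camera (adjusted p = 0.00384; adjusted p = 0.388 with an estimated correlation).

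In the granulocyte list the collagenase Mmp8 rose from 1598 ± 184 to 4166 ± 242 (log2 1.39, limma adjusted p = 0.00141), Mmp9 rose (1.20) and Ccr3 fell (-1.34) among 12 tested, and the same numbers passed when adjusted over the list alone. The neutrophil genes S100a8 and S100a9 read 274.2 ± 58 and 281 ± 49.4 in wt against 278.2 ± 84.8 and 261 ± 36.9 in the mutant and did not pass. Of the 22 T and NK cell markers in the table only 5 had enough reads, of which Cd4 (1.65) and Cd28 (0.80) rose and Il7r (-0.56) fell, or 2 and 3 when adjusted over the list alone. The dendritic cell gene Ccr7 fell (-1.18; 1 of 10 tested, or 3 lower and 2 higher when adjusted over the list alone). The mast cell gene Hdc fell from 41.92 ± 3.9 to 6.615 ± 0.333 (1 of 3 tested, and 1 when adjusted over the list alone). Collagen Col1a1 fell (-1.05; 1 of 4 mesothelial and fibroblast markers, or 2 when adjusted over the list alone). It was at the threshold (limma adjusted p = 0.0477) and was not called by edgeR (adjusted p = 0.0534), by limma-voom (0.068), with no filter on low values (0.0807), or without wt 1, wt 2, wt 3 or mutant 2 (0.099 to 0.168). Cd4, Cd28, Ccr7, Ccr3 and Mmp9 were not called without wt 1, wt 2 or wt 3 (0.0749 to 0.139), nor Il7r without wt 1 or wt 3 (0.0949 and 0.0807). Camera called none of these 5 lists (adjusted p = 0.43 for granulocyte, 0.831 for T and NK, 0.831 for dendritic, 0.56 for mast cell and 0.43 for mesothelial and fibroblast markers). The granulocyte median of -0.01 and mean of 0.16 differed in sign.

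Of 25 NF-kB inflammatory genes, the chemokine Ccl5 alone fell (-1.62, limma adjusted p = 0.0177), 1 also when adjusted over the list alone, but not without wt 1 or wt 3 (0.102 and 0.1). The NF-kB list median was -0.002 (camera adjusted p = 0.831), at -0.51 in mutant 1 and 0.58 in mutant 2, and 0.004 under TMM scaling. The wt medians were 0.0566, -0.127 and 0.0846 for wt 1 to 3, so the mutant medians lay on opposite sides of them. Among wt libraries, wt 2 lay nearest to mutant 1. On component 2 of a principal component analysis (19.6% of variance), wt 2 (-13.12) and mutant 1 (-31.71) stood on 1 side. On the other side stood wt 1 (14.38), wt 3 (14.13) and mutant 2 (16.33). Over all libraries the NF-kB list had adjusted p = 0.967 with an estimated correlation. In cholesterol and fatty acid synthesis, 0 of 24 genes passed limma at an adjusted or unadjusted p, adjusted over the list alone, or by edgeR, DESeq2 or limma-voom (median -0.07, camera adjusted p = 0.769). The median of that list was -0.48 without mutant 1 and 0.33 without mutant 2, each with 1 mutant library left. Its estimated correlation was 0.987 (adjusted p = 0.967 with an estimated correlation over all libraries). In nuclear-encoded oxidative phosphorylation, 0 of 25 genes passed limma, edgeR or limma-voom or adjusted over the list alone, 1 was lower by DESeq2, and 4 were lower and 1 higher at an unadjusted p (camera adjusted p = 0.236). In cytosolic ribosomal proteins, 0 of 31 genes passed limma, edgeR or limma-voom or adjusted over the list alone, 1 was higher by DESeq2 and 5 at an unadjusted p. That list had a median of 0.11 and was higher by camera (adjusted p = 0.0073; adjusted p = 0.911 with an estimated correlation), though not without mutant 2 (camera adjusted p = 0.288).

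Among the genes with the highest fold changes, Capn11, a calpain protease gene, stood at 314.1 and 620.9 normalized counts in the mutants against 0.90 to 1.85 in wt (log2 7.01, SE 0.354, limma adjusted p = 0.00021). With so few reads in wt the Capn11 value depended on the pseudocount, at 5.57 with 8 and 7.85 with 0.5. The translational regulator Samd4 (3.32), the replication-dependent histone gene H4c17 (3.61), the tetraspanning membrane gene Ms4a4a (3.11), the potassium channel Kcnj10 (2.53), the docking protein Gab1 (2.48), the prostaglandin-degrading enzyme Hpgd (2.40) and Mturn (2.13) rose too. Their levels differed between mutants 1 and 2, at 1296 and 349.8 normalized counts for H4c17, 1217 and 4278 for Ms4a4a, 205.5 and 603.9 for Samd4 and 587.2 and 1537 for Gab1. H4c17 was higher in mutant 1, which also had the higher Rn18s share (5.28% against 4.04%). Whether RNA carry-over raised H4c17 was not tested. Samd4, H4c17, Ms4a4a, Gab1 and Mturn were not called without wt 1, wt 2 or wt 3 (limma adjusted p = 0.0594 to 0.101), nor Kcnj10 without wt 1 or wt 2 (0.102 and 0.0741), nor Hpgd without wt 3 (0.0715). Among the lowest were Ly6a (-5.06), which encodes Sca-1, the endothelial lipase gene Lipg (-4.71), Ifi213 (-4.70), Apol9b (-4.67), Slfn4 (-4.55), Slfn1 (-4.48), Ifi206 (-4.46) and Phf11a (-4.15). Lipg fell from 542.6 ± 18.9 to 20.08 ± 10.4 (limma adjusted p = 0.000443).

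Of the 1288 genes called, 1158 were also called in the authors' deposited table. The mutant group held 2 libraries that differed more from each other (r = 0.985 across genes) than the wt libraries did (0.992 to 0.995), and the call counts changed with the library left out: 29 higher and 173 lower without wt 1, 80 and 286 without wt 2, 37 and 177 without wt 3, 2062 and 2929 without mutant 1, and 493 and 839 without mutant 2. Of the 84 genes chosen by rule and called, 47, 35 and 45 were not called without wt 1, wt 2 and wt 3. Fold changes could stay close all the same. With wt 1, wt 2 or wt 3 left out in turn, Cd163 had log2 fold changes of 1.406, 1.434 and 1.501, against 1.447 with all libraries. Those of Pcna were -1.1, -1.021 and -1.115, against -1.079. A lost call therefore need not mean that the wt library left out carried the difference.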

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

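TMM scaling and the pseudocounts of 0.5 and 8 were chosen after the data were seen. EdgeR with TMM factors was the main test fixed beforehand, and was made an alternative after the data were seen. The other alternatives were fixed beforehand. The interferon-stimulated genes kept a median of -1.95 to -2.07 under every alternative run, and 53 to 58 of them were called lower without any 1 library or with another tool, scaling, filter, prior or pseudocount. DESeq2 called 989 genes higher and 1276 lower, and the test against a 1.5-fold change 22 and 153; the 1.5-fold test asks for more than a difference, and the cause of the DESeq2 gain was not tested, though DESeq2 put 16.8% of its calls on unchanged genes in the simulation of 15231 genes. Leaving out 1 library gave 29 to 2062 genes higher and 173 to 2929 lower; without a mutant library the other is assumed to vary like wt. With the replicate block, 6 genes were higher and 75 lower, 35 of them interferon-stimulated; the numbers were not treated as pairing samples, since same-numbered libraries deviated with r = -0.228 and -0.362 across genes and number 1 joins a male with a female. Of 29 lists, 15 were called at the preset correlation and 1 with an estimated correlation. Unadjusted fry p was 5.81e-06 for interferon-stimulated genes, 0.000157 for erythroid and platelet markers, 0.000217 for GTPases, 0.000239 for MHC class I and 0.000694 for sensors. It was 0.0349 for glycolysis, 0.0404 for large macrophage markers, 0.0478 for interferons and receptors, and 0.055 and 0.058 for nucleotide and B cell lists. The other called lists had 0.0971 (unfolded protein), 0.099 (lysosome), 0.123 (DNA repair), 0.132 (cell cycle) and 0.295 (ribosomal proteins). The median of NF-kB inflammatory genes turned to 0.58 without mutant 1 (-0.51 without mutant 2), and that of cholesterol and fatty acid synthesis to 0.33 without mutant 2 (-0.48 without mutant 1); the cause was not tested. Of the named genes, 118 in all with 84 called, none reversed under an alternative where either that or the main test called it. A change of sign in genes that neither called was not counted. The test without X and Y genes was not run, because no such gene was analysed here. Depth limits genes under about 0.1 CPM, such as Ifnb1.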

Other observations

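The gene families and the marker levels below, and all tests of the interferon-stimulated and cell cycle patterns, were chosen after the results were seen; the tests of linked alleles were not. Several families of interferon-regulated genes fell in most tested members. Among 11 tested genes with symbols Ifi203 to Ifi214, which belong to the Ifi200 family of nucleic acid binding proteins on chromosome 1 and include the pseudogene Ifi203-ps, 10 fell and Ifi208 rose, from 2.64 ± 1.52 (SD, n = 3) to 59.85 ± 25.1 normalized counts (SD, n = 2; limma adjusted p = 0.00776). Aim2, a related gene without such a symbol, did not pass (-0.19, limma adjusted p = 0.143). All 8 tested Slfn genes, all 5 Phf11 genes and all 4 Trim30 genes fell, with median log2 fold changes of -1.52, -2.66 and -1.64. The Ms4a family of membrane proteins was split: Ms4a4a rose by a log2 of 3.11, Ms4a4c fell by 3.06 and the other 7 did not pass. Fc gamma receptors were split as well, with the activating Fcgr1 lower (-1.52), the inhibitory Fcgr2b higher (1.33) and Fcgr3 (0.66) and Fcgr4 (-0.96) not past the threshold. These counts were the same with TMM scaling and with edgeR on RLE factors, but members of such families can share reads.

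Gata6, the transcription factor that marks resident large peritoneal macrophages, had 0 reads in all 5 libraries, which allows at most 0.091 to 0.11 CPM in each. Timd4, a receptor of long-lived resident macrophages, also had 0 reads in all 5, and the resident markers Selp, Tgfb2 and Ltbp1 averaged 0.124, 0.0508 and 0.167 CPM. Other members of that list were abundant, such as Itga6 (354 CPM), Thbs1 (277 CPM) and Cd9 (174 CPM), and 18 of the 28 in the table had enough reads to test. In the same libraries the proliferation genes Mki67 and Top2a averaged 501 and 404 CPM, ranks 242 and 342 of 30478 genes. The chemokine receptor Ccr2, known from monocytes, averaged 607 CPM, lipoprotein lipase Lpl 3410 CPM and Gpnmb 4740 CPM. The macrophage genes Adgre1 and Lyz2 averaged 1830 and 8250 CPM. The 0 reads of Gata6 and Timd4 in each library argue against a sizeable share of resident large macrophages that express these genes. Itga6, Thbs1 and Cd9 were abundant all the same. Whether the libraries hold resident macrophages that lack Gata6 and Timd4 reads was not tested.

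The lower interferon-stimulated genes were weighed against carry-over of ribosomal RNA, fewer cells of another type, and age. If ribosomal RNA went with the fall at the same rate within wt, the wt library with the highest Rn18s share should stand 1.45 lower on the log2 scale than the one with the lowest (-1.45). It stood at 0.0113, so that trend was not seen within wt. This sets 1 library against 1 of another sex and age. The wt shares, 0.599% to 1.64%, lay below those of the mutants, 4.04% and 5.28%, so an effect at the higher shares stays open. If the mutant libraries held fewer cells of an interferon-responding type, its markers should fall together by about as much as the list. The lowest median among the lists of other cell types was -0.632 (mesothelial and fibroblast markers, 4 genes) against -1.99. Some of these lists had only 3 to 5 tested genes. Among 20 small macrophage and monocyte markers, 4 fell, including Plac8 (-3.33), and 3 rose, so a median can hide single falls. This test cannot exclude a loss of such cells. Age cannot be told apart from genotype, because no age is shared between groups: the 9-week wt library differed from the 13-week ones by 0.00645, but the mutants were 8 weeks old. The genotype remains an untested explanation, and the data cannot divide it between Samhd1 and Cgas.

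The lower cell cycle genes may rest largely on 1 mutant library, at a list median of -0.25 in mutant 1 and -1.44 in mutant 2. If mutant 2 decided the change, members should be called lower without it no more often than other genes, and 35% of them were, against 5.63% of genes outside the list; this rests on 1 mutant library assumed to vary like wt, so how far the fall depends on mutant 2 stays open. Ribosomal RNA carry-over would put the lower median in the mutant with the higher Rn18s share, mutant 1, but its median stood 1.19 above that of mutant 2. This sets 1 library against 1, and both had a higher share than wt, so it cannot decide about the fall from wt. Whether mutant 2 differs through the state of its cells or its preparation was not tested.

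Mice bred with 2 altered loci may also carry linked alleles of another strain, which could change neighbouring genes. Of 1190 called genes outside the interferon lists, 21 (1.76%) lay within 10 Mb of Samhd1 or Cgas, but had every gene tested there been called the share would have been 20.7%, so the majority set beforehand was out of reach and this test decides nothing. Of 305 genes tested in those windows, 6.89% were called (exact binomial interval 4.31% to 10.3%; 6.16% near Samhd1 and 8.51% near Cgas), against a median of 8.2% and a 95th percentile of 14.3% over 1000 other windows. The pooled share lay under that median, as set beforehand for no linked effect, but the share near Cgas lay above it and the interval, added afterwards, includes it, so a small effect on some neighbours stays open.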
